A study of Homo sapiens with 10 samples.

How the data were processed

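RNA was sequenced from cultures of primary human neural progenitor cells, grown from fetal brain and differentiated into neurons. The cells carried a lentivirus coding for a short hairpin RNA (shRNA) against ELAVL2, a neuronal RNA-binding protein, or for a control shRNA. The labels give 5 libraries with the ELAVL2 shRNA and 5 with the control shRNA, and call them independent replicates without saying whether they come from separate donors. One label has the cells harvested after 4 weeks of differentiation and another has RNA extracted 3 days after transduction. Read together, these would place the transduction 3 days before the end of the 4 weeks, but the labels do not state its time within the differentiation. Total RNA was depleted of ribosomal RNA, libraries were made with a TruSeq kit, and the order of extraction and sequencing was randomised, per the labels.

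The deposited values are RPKM, computed by the authors for 60070 Ensembl gene IDs in each library. RPKM are reads scaled to gene length in kilobases and to a library total, here close to the sum of reads assigned to genes. The submitters name HTSeq and genome build GRCh37. The aligner, the gene annotation, the gene lengths and the read length are not given in the sources used here. Splicing was not analysed here, since the values are per gene.

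Gene names were paired with the IDs through GENCODE release 29, which holds 56494 of the 60070 IDs. Of 94 genes checked against a newer table of names, 3 histone genes have another symbol there, and the older symbols are printed. The IDs include none of the 37 mitochondrially encoded genes of that annotation. A total of 513 IDs, of the Y chromosome and of X inactivation, were left out of every analysis, among them 44 of the 18661 genes past the minimum level.

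Whole read numbers were recovered from the RPKM values, because genes with few reads take only values that are whole multiples of a step set by gene length and library total. Between 98.1% and 98.4% of the low values in each library were whole multiples to within 0.01 of a read. With the GENCODE length, 16308 genes (87.4% of the 18661) gave whole reads to within 0.001, and for the other 2353 the length was searched. The recovered totals ran from 57140408 to 97001599 assigned reads per library. The recovered reads of the 18661 genes summed to between 99.5% and 99.6% of these totals. Intervals computed from reads cover counting error only.

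The comparison set the 5 libraries labelled knockdown against the 5 controls with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend) on log2(RPKM + 0.5), without further scaling. The 18617 genes with a mean of at least 0.5 RPKM were tested, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold intervals are 95% intervals on this scale, where the pseudocount draws folds of genes near 0.5 RPKM towards 1. An exact two-sided permutation test over the 252 arrangements of the libraries stands beside it for named genes; 0.00794 is the smallest p it can give. Each p measures the spread between these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

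A set of 31 gene lists (cell types, neuronal functions, stress responses and signs of RNA quality) was fixed before the data were examined, as were the test, the thresholds, the rule for named genes and 23 alternative settings. The 26 lists with at least 5 tested members were compared with all other genes by camera in limma with a preset correlation between genes of 0.01, adjusted over the lists. Beside it stand camera with a correlation estimated for each list, fry, and an exact permutation of the mean of the members. The genes named by rule were the 4 ELAVL genes, up to 10 called genes in each direction with a mean of at least 1 RPKM and groups that do not overlap, and for each list up to 2 called members in each direction or, with none called, the member with the smallest p. Where fewer than 5 genes were called in a direction, the 10 with the smallest p among genes with a mean of at least 1 RPKM were named in their place, as genes that did not pass. Clones, pseudogenes, small RNAs and histones were left out of these 10. Other genes named in the text, such as cell type markers with high levels, were chosen after their values were seen.

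The test was tried on simulated data from regrouped libraries, over 20 draws. In each draw 200 genes with a mean of at least 1 RPKM were raised or lowered, 50 by each fold. The test recovered 33.5% of 1.25-fold changes, 77.9% of 1.5-fold changes, 95.4% of 2-fold changes and 99.2% of 4-fold changes. With 200 genes changed at once, the Benjamini-Hochberg cut is looser than where 1 gene is called. These shares therefore overstate the recovery where few genes differ, a case that was not simulated. A median of 4 other genes were called per draw, with 56 in the highest draw. In these draws no list was changed as a set, though the 200 genes could include members of lists. There camera with the preset correlation called a median of 6 lists and 14 in the highest.

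The alternatives were other pseudocounts, filters, scalings, variance models, thresholds and list tests, the replicate number as a block, and each library left out in turn. Another 6 settings were added after the data were seen. These were voom on the recovered reads without and with quality weights, the removal of both libraries that stand apart from the rest, protein-coding genes only, removal of a gene length trend in each library, and the exact test of the lists.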

Results

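Gene-level RNA levels were measured in 10 libraries of differentiated human neural progenitors, 5 with an shRNA against ELAVL2 and 5 with a control shRNA. The libraries labelled knockdown held 88192793, 83284270, 88432258, 57140408 and 67957060 assigned reads for replicates 1 to 5. The controls held 91109582, 63166021, 82443891, 95881316 and 97001599.

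The cultures held neurons and glia together, by marker genes chosen for mention after their levels were seen. Neuronal genes were among the highest, with DPYSL3, a growth cone protein, at a mean of 293 RPKM over the 10 libraries, DCX, a microtubule protein of migrating neurons, at 286 RPKM and MAP1B at 243 RPKM. The interneuron transcription factors DLX1 (180 RPKM) and DLX2 (116 RPKM), the interneuron calcium-binding protein CALB2 (139 RPKM) and GAD1, an enzyme that makes GABA (53.4 RPKM), were abundant. Among markers of excitatory cortical neurons, FEZF2 of deep layers was at 5.01 RPKM. ETV1 (68.7 RPKM) and POU3F3 (74.9 RPKM) were the highest of the deep-layer and upper-layer lists. The median members of these lists stood at 2.77 and 1.79 RPKM. Astrocyte and radial glia genes reached levels as high as neuronal ones, with the astrocyte filament protein GFAP at 468 RPKM, the water channel AQP4 at 55.1 RPKM, the progenitor transcription factor SOX2 at 173 RPKM and PTPRZ1, a phosphatase of radial glia, at 178 RPKM. The median member stood at 66.9 RPKM for pan-neuronal structure, 31.8 RPKM for astrocytes, 20.4 RPKM for radial glia and 9.84 RPKM for interneurons. For the oligodendrocyte lineage it stood at 0.0506 RPKM and for intermediate progenitors at 0.00523 RPKM. No microglial gene reached the minimum for testing, and HLA-DRA was the highest of the 13 at 0.447 RPKM. Of 19 endothelial, mural and fibroblast genes 3 reached it, with PDGFRB highest at 5.26 RPKM.

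**Figure D1:**
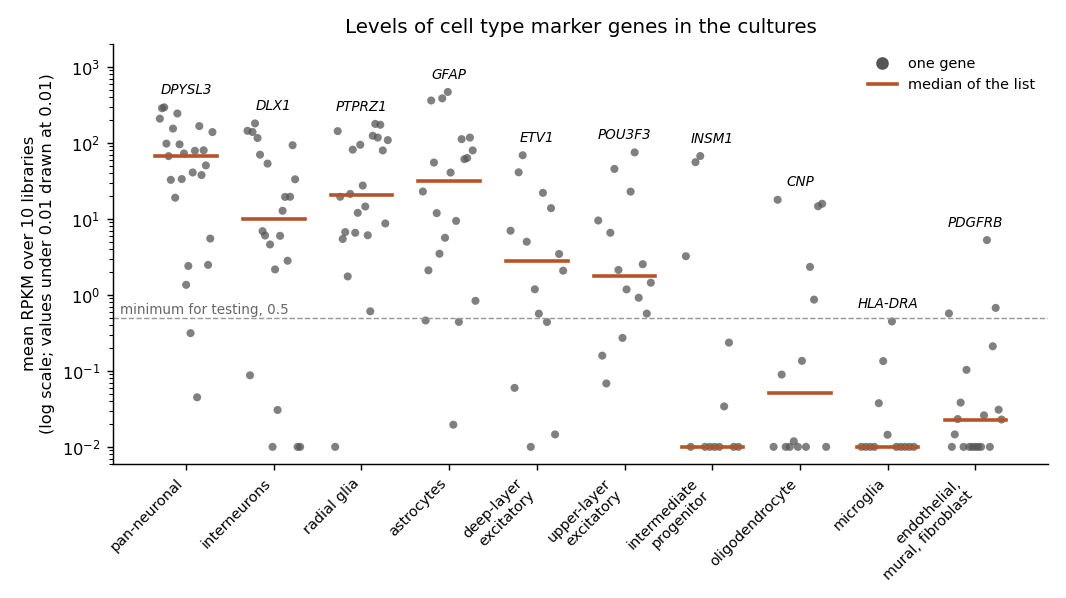
Mean RPKM over the 10 libraries (log scale) of each gene in the 10 cell type lists, with the median of each list as a bar and the highest gene named. Pan-neuronal, interneuron, radial glia and astrocyte genes reached the highest levels, up to 468 RPKM for GFAP, while the median microglial gene lay under 0.01 RPKM.

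The comparison of the ELAVL2 shRNA with the control shRNA asks which genes depend on ELAVL2 in human neurons, and the level of ELAVL2 itself comes before it. ELAVL2 (ENSG00000107105) was not lower in the libraries labelled knockdown. Its mRNA stood at 11.99 ± 0.608 RPKM (SD, n = 5) there and at 11.80 ± 0.669 RPKM (SD, n = 5) in the controls. The libraries labelled knockdown ranged from 11.5 to 12.9 RPKM and the controls from 11.1 to 12.8 RPKM. The log2 fold change was 0.02 with an SE of 0.05 (limma adjusted p = 0.901), and the exact permutation test gave p = 0.571. The 95% interval of the fold ran from 0.940 to 1.10, so a fold of 0.8 lay outside it. Between 3800 and 6313 reads per library lay behind these values. Without knockdown 4 the log2 fold change was -0.0046, with adjusted p from 0.692 to 0.998 over the 24 alternatives.

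The other members of the family did not pass the test either. ELAVL1, the member expressed in all tissues, had a log2 fold change of 0.03 (21.4 against 20.9 RPKM, adjusted p = 0.850). ELAVL3, a neuronal member and the most abundant of the 4, had -0.12 (81.2 against 87.7 RPKM, adjusted p = 0.652). ELAVL4, the third neuronal member, had -0.02 (3.21 against 3.24 RPKM, adjusted p = 0.952), and its sign turned when knockdown 1 (0.046), knockdown 4 (0.0027) or control 5 (0.0084) was left out. Every direction given from here on is between libraries as labelled, with ELAVL2 at a similar level in both groups.

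**Figure D2:**
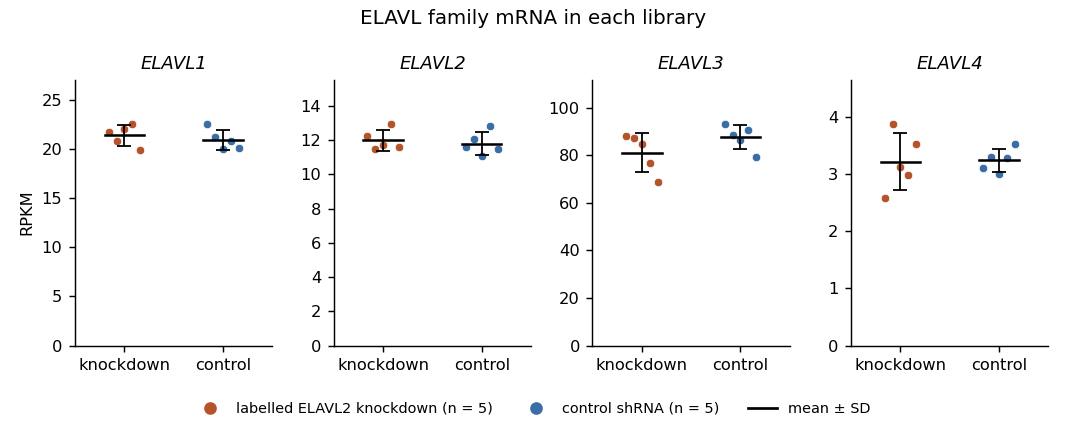
RPKM of ELAVL1, ELAVL2, ELAVL3 and ELAVL4 in each of the 10 libraries (points), with mean and SD (bars, n = 5 per group). ELAVL2 lay between 11.1 and 12.9 RPKM in all 10, and the groups overlapped for each of the 4 genes.

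Among single genes, SPARCL1 rose in the libraries labelled knockdown and was the only gene called of 18617 tested. SPARCL1 (ENSG00000152583), an astrocyte-secreted matrix protein that promotes the formation of synapses, stood at 1.13 ± 0.0788 RPKM (SD, n = 5) against 0.540 ± 0.0924 RPKM (SD, n = 5) in the controls, a ratio of means of 2.10. All 5 libraries labelled knockdown lay above every control. Its log2 fold change was 0.65 with an SE of 0.07 (adjusted p = 0.0293), a fold of 1.41 to 1.76 on the scale with the pseudocount (95% interval), and the exact permutation p was 0.00794. Its level was low, with 108 to 360 reads per library and a mean of 0.835 RPKM, so it was not tested at a minimum of 1 RPKM.

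The call of SPARCL1 was lost without any 1 of 9 libraries, with adjusted p of 0.135, 0.0870, 0.0803, 0.172 and 0.0672 without knockdown 1 to 5, and 0.135, 0.155, 0.0653 and 0.163 without controls 1 to 4. Without control 5 it was 0.0259. In all it was lost under 12 of 23 alternatives, where adjusted p ran from 0.000640 to 0.249 over the 23. Settings that lost it included no filter on low values (0.248), the replicate number as a block (0.249) and removal of both libraries that stand apart (0.132). The log2 fold change of SPARCL1 in the fits that left out libraries ran from 0.62 to 0.70, beside 0.65 with all libraries.

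No gene was called lower by the planned test. limma called 0 genes lower, with 840 lower and 700 higher at an unadjusted p under 0.05, together 1540 or 8.27% of the genes where 931 would be expected. voom on recovered reads called 0 genes lower and 2 higher, and voom with quality weights called 2 lower and 5 higher. Libraries of the groups did not overlap for 249 genes that were higher and 119 that were lower, 1.98% of those tested, where chance gives 0.794%. The second smallest adjusted p was 0.164. The median 95% interval reached 1.12-fold to either side.

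Among genes with a mean of at least 1 RPKM, the 10 named for the smallest p among higher values did not pass the test. All 5 libraries labelled knockdown lay above every control for each. A choice by smallest p favours such a separation, which 249 of the tested genes had. SEMA5A, a semaphorin that guides axons, stood at 22.3 ± 4.59 against 12.9 ± 2.45 RPKM (SD, n = 5 each), a log2 fold change of 0.76 (adjusted p = 0.326). TSPAN12, a membrane protein of Norrin signalling, had 0.49 (1.76 against 1.11 RPKM, adjusted p = 0.245). SHISA6, an auxiliary subunit of AMPA receptors, had 0.50 (1.61 against 1.01 RPKM, adjusted p = 0.320), and CXCL12, a chemokine that guides migrating interneurons, 0.40 (4.85 against 3.55 RPKM, adjusted p = 0.245). The other 6 were RAB31, LAMP2, WWTR1, LIPG, SYNM and BHLHE40, with log2 fold changes between 0.23 for BHLHE40 and 0.30 for RAB31. voom with quality weights called TSPAN12 (adjusted p = 0.0408), SHISA6 (0.0408) and BHLHE40 (0.0440), where the ranges over 24 alternatives were 0.0408 to 0.829, 0.0408 to 0.829 and 0.0440 to 0.829.

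At the same minimum of 1 RPKM, the 10 named for the smallest p among lower values did not pass either. SHISA8 stood at 2.10 ± 0.250 against 2.83 ± 0.305 RPKM (SD, n = 5 each), a log2 fold change of -0.35 (adjusted p = 0.489). GAD2, the synaptic enzyme of GABA synthesis, had -0.19 (4.27 against 4.94 RPKM, adjusted p = 0.509), MAST1, a microtubule-associated kinase, -0.18 (24.1 against 27.4 RPKM, adjusted p = 0.505), and the semaphorin receptor PLXNA3 -0.17 (23.9 against 26.8 RPKM, adjusted p = 0.509). The remaining 6 were CENPX, DGAT1, WDR86, PTPN5, TUBG2 and INPP5E, between -0.25 for CENPX and -0.20 for INPP5E.

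**Figure D3:**
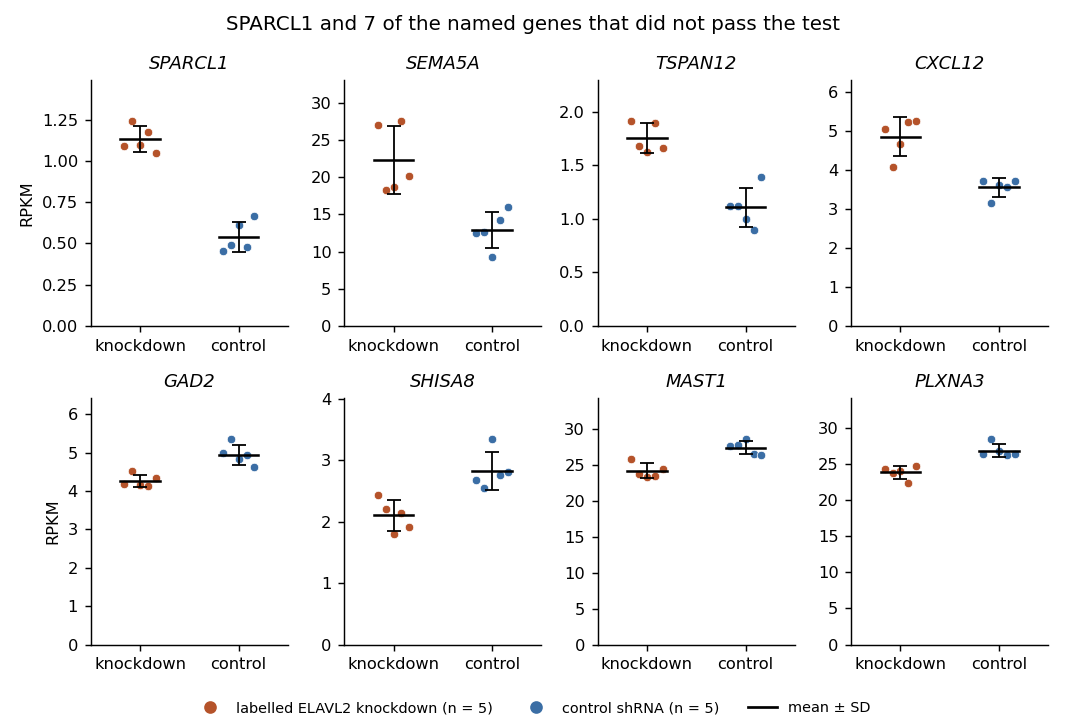
RPKM in each library (points) of SPARCL1, the gene that passed the test, and of 7 genes named for small p that did not. Bars give mean and SD (n = 5 per group). For each gene all 5 libraries labelled knockdown lay on the same side of all 5 controls; the panel of SPARCL1 spans 0.451 to 1.24 RPKM.

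Among gene lists, markers of upper-layer neurons, oligodendrocytes, astrocytes and radial glia, cell division, autism risk and ELAVL-bound genes were called higher in the libraries labelled knockdown, and replication-dependent histones lower. These were 8 of 26 lists, 7 higher and 1 lower, by camera with a preset correlation, and none of the 8 held with an estimated correlation (0 lists). In regrouped libraries where no list was changed as a set, the same test called a median of 6 lists. Its directions are relative to all other genes, and the median log2 fold change of all tested genes was -0.018. fry and the exact permutation test of the list mean called 0 lists, with 3 at an unadjusted exact p under 0.05. fry's test of change in either direction called 3 lists, astrocytes, upper-layer neurons and GABA. The astrocyte list includes SPARCL1, and fry was not run without this gene. Over all genes tested 1 member of any list was called, SPARCL1, and adjusted over the list alone 13 distinct members were.

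Upper-layer excitatory neuron genes were higher as a list, with a median log2 fold change of 0.12 and 9 of 11 members above 0 (camera adjusted p = 0.000283). With an estimated correlation the list was not called (adjusted p = 0.175 with an estimated correlation), and the unadjusted exact p was 0.0159. RASGRF2, an activator of Ras in upper-layer neurons, had 0.29, and MEF2C, a transcription factor of maturing neurons, 0.23; adjusted over the list alone these 2 members passed. LHX2, a progenitor transcription factor, had 0.20 and LMO4 0.12. The most abundant member, POU3F3 at 74.9 RPKM, had -0.03, and 4 of the 5 libraries labelled knockdown scored above every control.

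The oligodendrocyte lineage list was higher (camera adjusted p = 0.00823), with a median of 0.17 and 5 of 5 tested members above 0. Of its 14 genes, 9 lay under the minimum level and were not tested. SOX10 was among them, listed at 0, and whether its RNA was absent is open. The call was lost with an estimated correlation (adjusted p = 0.175 with an estimated correlation), and the unadjusted exact p was 0.0238. Of the 5 libraries labelled knockdown, 3 scored above every control, where control 5 was at 0.13. OLIG1, a transcription factor of oligodendrocyte precursors, stood at 2.97 ± 0.987 against 1.70 ± 0.489 RPKM (SD, n = 5 each), a log2 fold change of 0.64. OLIG2, also needed for motor neurons, had 0.57 (1.14 against 0.592 RPKM, adjusted p = 0.489), and adjusted over the list alone these 2 members passed. PDGFRA, a receptor of precursors, had 0.17 (15.5 against 13.8 RPKM), while CNP, an enzyme of myelin, had 0.03 and MBP was at 0.0118 RPKM.

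Astrocyte and radial glia genes were higher as lists. The astrocyte list had a median of 0.08 with 11 of 17 members above 0 (camera adjusted p = 0.0259). Its call was lost with an estimated correlation (adjusted p = 0.540 with an estimated correlation), and the unadjusted exact p was 0.365. Beside SPARCL1, the glutamate transporter SLC1A2 had 0.27 and the hyaluronan receptor CD44 0.25, while FGFR3 had -0.29 and APOE, which carries lipids, -0.24. The 16 tested members other than SPARCL1 had a median of 0.069. At a minimum of 1 RPKM, which left out SPARCL1, camera did not call the astrocyte list. Without 1 library the astrocyte call was lost for knockdown 2 (adjusted p = 0.125), knockdown 3 (0.225), control 2 (0.0649) and control 4 (0.0639). The radial glia list had a median of 0.04 with 15 of 21 members above 0 (camera adjusted p = 0.00953). It was not called with an estimated correlation (adjusted p = 0.540 with an estimated correlation), and its unadjusted exact p was 0.222. Nor was it called by camera without knockdown 2 (0.0624) or knockdown 3 (0.109). NOTCH2, a receptor that maintains progenitors, had 0.27 and PTPRZ1 0.23. Astrocyte and radial glia scores were lowest in knockdown 4 (-0.12) and control 3 (-0.09) and both highest in knockdown 3 (0.17 and 0.11).

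Cell division genes were higher as a list (camera adjusted p = 0.00953), with a median of 0.07 and 24 of 30 members above 0. This call was lost with an estimated correlation (adjusted p = 0.763 with an estimated correlation), and the unadjusted exact p was 0.532. RRM2, a subunit of ribonucleotide reductase, had the smallest p at 0.11 (adjusted p = 0.633). The call was lost without knockdown 2 (adjusted p = 0.192), control 3 (0.0623) or control 4 (0.193), and the list's scores in the libraries labelled knockdown lay within those of the controls, -0.15 in control 4 to 0.21 in control 5. Replication-dependent histone genes, listed as a sign of RNA quality, went the other way. Their median was -0.18, with 13 of 14 members below 0 (camera adjusted p = 0.000283). With an estimated correlation the adjusted p was 0.540, and the unadjusted exact p was 0.0238. Of the 5 libraries labelled knockdown, 3 scored below every control, with knockdown 1 (-0.27) and knockdown 4 (-0.18) lowest. The other tested lists of RNA quality, ribosomal proteins and nuclear-retained RNAs, had medians of -0.05 and -0.16 and were not called. HIST2H2BE stood at 58.3 ± 6.48 against 70.5 ± 6.06 RPKM (SD, n = 5 each), a log2 fold change of -0.27. HIST2H2AC had -0.27 too, and these 2 histones passed when adjusted over the list alone.

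Autism risk genes and mRNAs reported to be bound by ELAVL proteins were lists tied to the study's subject. Of 53 tested autism risk genes 43 had estimates above 0, with a median of 0.03 (camera adjusted p = 0.00823). That call was lost with an estimated correlation (adjusted p = 0.763 with an estimated correlation), and the unadjusted exact p was 0.492. RELN, a secreted guide of neuronal migration, had 0.36 (3.20 against 2.42 RPKM) and the NMDA receptor subunit GRIN2B 0.31 (3.73 against 2.95 RPKM), while the synaptic scaffold SHANK3 had -0.12. None of these 3 passed over all genes or adjusted over the list alone. The list turned lower without control 3 (adjusted p = 0.877), the library with its lowest score (-0.21), and lost its call with array weights (0.345), in a range of 0.000724 to 0.930 over 27 alternatives. The ELAVL-bound list had a median of 0.06 with 9 of 13 members above 0. It was called by camera (adjusted p = 0.0457), but not with an estimated correlation (adjusted p = 0.540), and its unadjusted exact p was 0.317. NOVA1, a splicing regulator, had 0.11, and GAP43, a growth cone protein whose mRNA ELAVL4 stabilises, -0.03. That call was lost without knockdown 1 (adjusted p = 0.209), knockdown 4 (0.114), control 2 (0.123), control 4 (0.0726) or control 5 (0.0714).

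Of these 8 lists, 5 lost their call under other settings as well. Without both libraries that stand apart, control 3 and knockdown 5, adjusted p was 0.930 for autism risk, 0.0553 for radial glia and 0.196 for cell division. With the gene length trend removed it was 0.568 for autism risk, 0.109 for ELAVL-bound mRNAs and 0.0516 for astrocytes. voom with quality weights gave 0.401 for autism risk and 0.0521 for cell division, protein-coding genes only gave 0.0828 for ELAVL-bound mRNAs and 0.0533 for astrocytes, and a minimum of 1 RPKM gave 0.162 for astrocytes. Over 27 alternatives adjusted p ran from 0.00668 to 0.782 for ELAVL-bound mRNAs, 0.000517 to 0.782 for radial glia, 5.27e-06 to 0.783 for cell division and 0.000735 to 0.782 for astrocytes.

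Lists of neuronal function were not called. Neuronal splicing regulators (camera adjusted p = 0.567), with NOVA1 as the member of smallest p, had a negative median (-0.0041) and mean (-0.0079) where the test pointed higher. A list can point higher with values below 0, since the test is against all other genes, and the median of all tested genes was -0.018. Pan-neuronal structure (0.663) had a median of -0.05, with STMN2, a growth cone protein, at 0.20. Presynaptic release (0.763) held SYPL1 at 0.21. Glutamate receptors and postsynaptic density (0.0951) held DLGAP1, a scaffold protein, at 0.26, and voltage-gated ion channels (0.349) the sodium channel subunit SCN4B at 0.24, each passing when adjusted over the list alone. In the GABA list (0.150) GAD2 and ABAT, which degrades GABA, at 0.17, passed when adjusted over the list alone. In axon guidance (0.0539) SEMA5A and PLXNA3 did. Deep-layer neurons (0.315) held LMO3 at 0.11. Interneurons (0.930) had a median of -0.01 and a mean of 0.0059, where the test pointed higher, and GAD2 passed when adjusted over that list alone.

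Stress and metabolic lists were not called either. The interferon response, which can follow a virus or double-stranded RNA, had a camera adjusted p of 0.188, with USP18 at 0.22, and p53 targets had 0.0828, with ZMAT3 at 0.23. The unfolded protein response (0.913) held CANX at 0.15, and immediate-early genes (0.920) BTG2 at 0.17. Hypoxia and glycolysis (0.738) held ALDOC at -0.17, with a median of -8.9e-05 and a mean of 1.5e-05 where the test pointed higher. Cholesterol synthesis (0.913) held SC5D at 0.16, with a negative median (-0.04) and mean (-0.01) where the test pointed higher. Ribosomal proteins (0.0708) held RPS21 at -0.15, the respiratory chain (0.0868) NDUFS1 at 0.09, and nuclear-retained RNAs (0.0868) GAS5 at -0.15. Too few members were measured to test the ELAVL family (4), intermediate progenitors (3, with HES6 at -0.04), endothelial, mural and fibroblast genes (3, with TAGLN at -0.20), microglia (0) and mitochondrially encoded mRNAs (0 of 13).

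**Figure D4:**
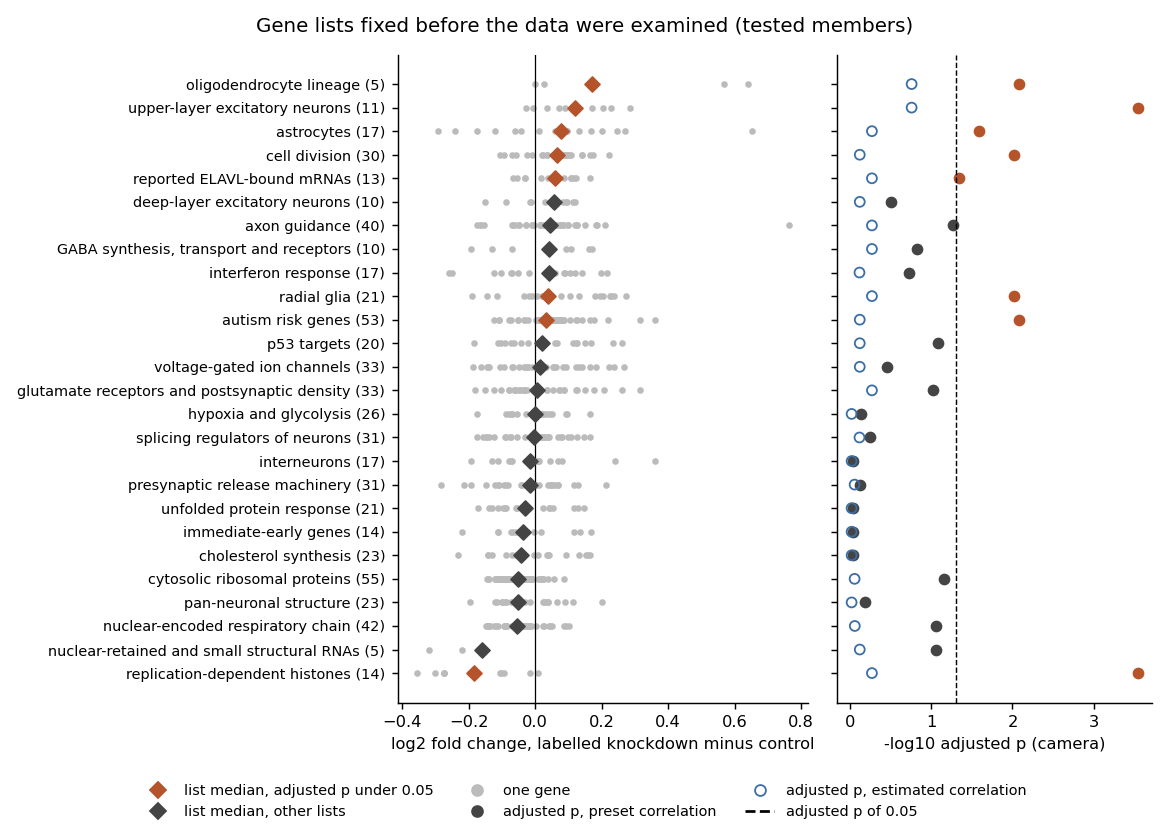
Left, log2 fold change of each tested member (grey) and list median (diamond) for the 26 lists, labelled knockdown minus control, with the number tested in parentheses. Right, -log10 of the camera adjusted p with the preset correlation (filled) and with an estimated one (open); 8 lists pass the dashed line with the preset correlation and 0 with an estimated one.

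The libraries did not separate by label. Pearson correlations of log2 values across genes ran from 0.985 to 0.996 over 45 pairs of libraries, with a median of 0.992 both within groups and between them; genes are not independent replicates. The leading 3 principal components held 26.2%, 23.0% and 15.1% of the variance, and their exact permutation p for a difference between groups was 0.286, 0.159 and 0.0952. Control 3 lay farthest out on the second component (28.0), knockdown 5 (19.5) and knockdown 3 (-17.9) at the ends of the leading one, and control 2 (20.3) on the third. Control 3 and knockdown 5, taken as the libraries that stand apart, had the lowest array weights (0.274 and 0.427). In control 3 longer protein-coding genes had lower values, with a Spearman rho across genes of -0.55, where the other 9 libraries ran from -0.13 to 0.28.

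**Figure D5:**
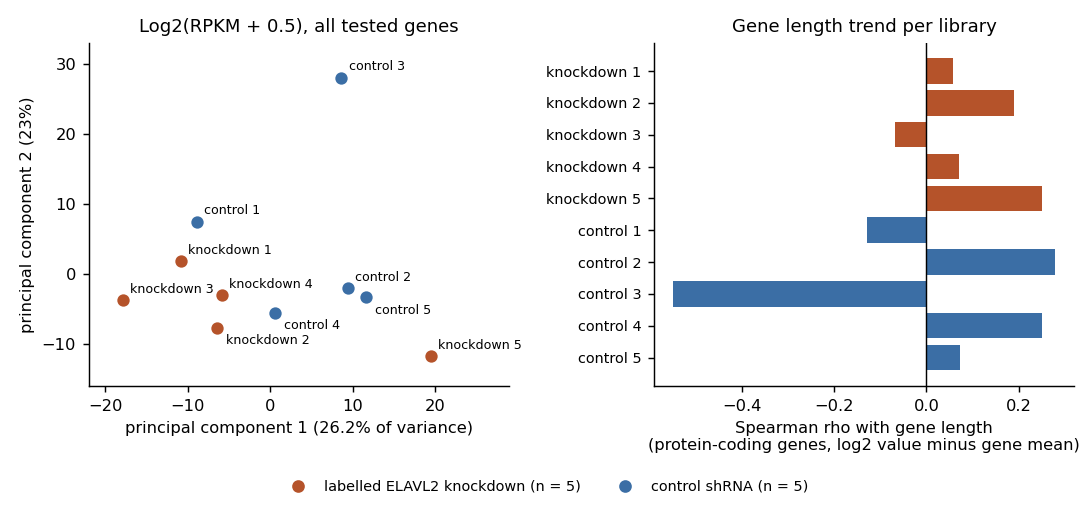
Left, the 10 libraries on the leading 2 principal components of log2(RPKM + 0.5). Right, Spearman rho across protein-coding genes between gene length and a library's log2 value minus the gene's mean; control 3 reached -0.55.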

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

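The tests of a label swap, of precision, of astrocytes and of counting error were chosen after the results were seen, as were the settings that left out both libraries standing apart or removed a gene length trend. The counts over other splits of the libraries were planned before.

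ELAVL2 mRNA was at a similar level in the libraries labelled knockdown and the controls. A swap of labels between some libraries that hid a fall of ELAVL2 mRNA would leave a high and a low class. The highest library had 1.17 times the level of the lowest, under the 1.5 set for such a swap. Where the shRNA left the mRNA unchanged, swapped labels would not show in ELAVL2, so a swap as such was not excluded. Too little precision to see a fall of 20% is argued against by the lower end of the 95% interval of the fold, 0.940, above 0.8. An shRNA that lowered the protein without lowering its mRNA may leave the mRNA at this level. So may a low share of transduced cells, the time between transduction and harvest, or values from other cultures than the labels name. None of these was tested.

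SPARCL1 was higher in all 5 libraries labelled knockdown. More astrocytes would raise the other 16 tested members of the astrocyte list, whose median log2 fold change was 0.069 with an SD of 0.17, below the 0.33 that stands for 0.5 times the change of SPARCL1; the abundant GFAP differed by 0.01. Counting error is argued against by 95% Poisson intervals, since the lowest bound of the libraries labelled knockdown was 1.21 times the highest bound of the controls. In 4 of 100 splits of the libraries, the real one included, as many genes were called as the real 1. The highest of the other splits called 1. This count takes in any called gene, so it does not test SPARCL1 itself, and only 100 of 126 splits were run. The splits were drawn without regard to replicate numbers, and a pairing by number is open. With the replicate number as a block SPARCL1 was not called (limma adjusted p = 0.249). Chance was therefore not excluded for SPARCL1. Any effect of the shRNA on SPARCL1 remains a hypothesis, since ELAVL2 mRNA was not lower, and a difference in the state of astrocytes was not tested.

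The gene lists called with the preset correlation could be a product of chance: 60 of 100 splits called as many as the real 8, the highest other split called 15, and the median other split 8. With a gene length trend removed in each library 5 of the 8 lists were still called, and 5 of 8 without both libraries that stand apart (control 3 and knockdown 5). Both counts lie between the bounds of 2 and 6 set for these settings. Neither explanation was therefore excluded, and neither can be told apart from an effect of the shRNA. The number of genes at an unadjusted p under 0.05 gave the same reading, since 16 of 100 splits had as many as the real 1540, the highest other had 3269 and the median other 623, so that chance was not excluded.

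Single values were listed where a library lay far from the other 4 of its group, with a gap over 0.71 of the group's range. This held for 19 of 244 groups of values (7.79%), where chance gives about 5%. Control 3 held 8 of them, control 5 held 5, control 2 held 3 and knockdown 5 held 3.

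In control 3, far from the other controls, the small nucleolar RNA host gene GAS5 was high at 5.55 RPKM and the smooth muscle protein TAGLN at 0.948 RPKM. The glutamate transporter SLC1A2 was low at 46.8 RPKM and the complex I subunit NDUFS1 at 15.8 RPKM. The mean log2 deviation of the autism risk list was low at -0.21, of axon guidance at -0.13 and of glutamate receptors and postsynaptic density at -0.073, and that of the respiratory chain was high at 0.21. In control 5 OLIG2 was high at 0.806 RPKM, beside high scores of the oligodendrocyte lineage (0.13) and radial glia (0.086), a low score of pan-neuronal structure (-0.10) and a low HIST2H2BE (60.0 RPKM). In control 2 CXCL12 was low at 3.14 RPKM, the interferon-induced USP18 was low at 0.543 RPKM and PLXNA3 was high at 28.4 RPKM. In knockdown 5 the lipid enzyme DGAT1 was high at 9.05 RPKM, the noncoding MEG3 was high at 16.8 RPKM, and the sum of all RPKM values was low at 345424.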

How the results depend on the processing

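Of 29 settings, the 6 named as added were chosen after the data were seen. The log2 fold change of ELAVL2 was 0.02 and ran from -0.0046 (without knockdown 4) to 0.051 over 24 alternatives, none passing. The number of genes changed was 1, higher, in the test as planned. It was 0 without a filter on low values (2850 genes at an unadjusted p under 0.05), 0 at a minimum of 1 RPKM (1373), 0 with the replicate block (2202) and 0 without both libraries that stand apart (2099). It was 2 with quantile normalization, 2 with voom, 2 with protein-coding genes only, in each case higher, and 7 with voom and quality weights, 5 higher and 2 lower. With each library left out in turn it ran from 0 to 1, higher, with 0 lower throughout, and was 1 only without control 5. Fewer genes tested removed SPARCL1 at the minimum of 1 RPKM, and fewer libraries lower the power; for the other settings the cause was not tested. SPARCL1 passed in 11 of 23 alternatives, among them 1 of the 10 that left out a library, with log2 fold changes of 0.47 to 1.15. With the replicate block, which leaves every fold change as it is in this balanced design, SPARCL1 was not called (adjusted p = 0.249) and the ELAVL-bound list lost its call (0.0536); 10 lists were called, among them 7 of the 8. The labels do not say that a replicate number marks a shared donor or batch. Deviations from the group means correlated at 0.363, 0.101, 0.0033, -0.038 and 0.485 between the libraries of numbers 1 to 5. For numbers 1 and 5, and for no other number, each library correlated best with its own number in the other group, so a pairing is not shown for all numbers and is open for these. The number of lists called, 8, became 0 with an estimated correlation, 0 with fry, 0 with the exact permutation and 5 with the length trend removed, and ran from 6 to 10 with a library left out. The upper-layer, histone and oligodendrocyte lists were called in all 30 fits that left out a library. No fit left out knockdown 1 and knockdown 4 together, the libraries with the lowest histone scores. Of 215 values for the 8 called lists, 163 kept the call. The autism risk list ran from adjusted p 0.000724 to 0.877 with a library left out and turned lower without control 3 (0.877). ELAVL4 ran from -0.080 to 0.046 with a library left out. HES6 turned to 0.019 with array weights, 0.029 with voom and quality weights and 0.070 without both libraries that stand apart, and ran from -0.12 to 0.057 with a library left out; the cause was not tested. Of 1098 values for the other named genes, 1087 kept their direction and side of the threshold, 8 reversed and 3 passed. Genes near 0.5 RPKM rest on few reads, such as SPARCL1 with 108 to 360 per library, and a limit by depth was not tested.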

Other observations

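The observations here were chosen after the values were seen, and no test between groups was planned for them. Genes of cholesterol synthesis moved together between libraries regardless of label. Their mean log2 deviation ran from -0.34 in knockdown 2 to 0.39 in knockdown 4, with a correlation between members of 0.844, the highest of the 26 lists, and the groups differed by -0.01. Nuclear-retained RNAs such as MALAT1 and MEG3 ran from -0.58 in knockdown 3 to 0.47 in knockdown 5, with a correlation of 0.814. LUC7L3, a splicing factor, ran from 25.2 to 86.8 RPKM and PNISR, a nuclear serine and arginine-rich protein, from 11.3 to 40.0 RPKM, with their lowest and highest values in the same pair of libraries. In control 3 ZBTB20, a transcription factor of astrocyte formation, was at 0.816 RPKM and NKAIN3 at 3.52 RPKM, the lowest of the 10 libraries, where knockdown 3 had 5.14 and 17.5 RPKM. NMB, which codes for the peptide neuromedin B, ran from 77.7 RPKM in knockdown 1 to 211 RPKM in knockdown 3.

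Some abundant genes were assigned lower RPKM than a pseudogene copy, over the 10 libraries. Whether the reads came from the gene or from its copy was not tested. EEF1A1P5 had 5.28 times the RPKM of EEF1A1, the translation elongation factor, and RPL13AP5 had 19.6 times and RPL41P1 9.07 times that of the ribosomal protein genes RPL13A and RPL41. TMSB10P1 had 1.15 times the RPKM of TMSB10 (1102.6 ± 157.5 against 964.6 ± 145.1 RPKM, SD, n = 10 libraries). Pseudogenes held between 11.4% and 12.8% of reads in each library, and pseudogenes of mitochondrial genes 3.05% to 4.07%. XBP1, a transcription factor of the unfolded protein response, and SOX10, of oligodendrocytes, were listed at 0 in all libraries. Whether these values mean absent RNA or reads not assigned to the gene was not tested.

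Beside TSPAN12, SHISA6 and BHLHE40, which voom called with quality weights, other genes called by voom and not by the planned test were PARM1 (1.00 against 0.594 RPKM), a mucin-like membrane protein, and with quality weights also the signal recognition particle pseudogenes RN7SL4P (371 against 603 RPKM) and RN7SL5P (280 against 444 RPKM). In the planned test the adjusted p of PARM1, RN7SL4P and RN7SL5P were 0.207, 0.402 and 0.451. RN7SL1 and RN7SL2, the genes these pseudogenes resemble, were listed at 0 in all libraries.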
